A study of Mus musculus with 8 samples.

How the data were processed

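RNA-seq of cultured mouse kidney tubular epithelial cells was analysed from the processed table of the series, with 4 libraries from control mice and 4 from mice lacking Aldh2 in tubular epithelium. The cells were untreated. Groups were taken from the sample titles. The genotype field of the 4 knockout samples carries running gene names (ALDH2, ALDH3, ALDH4 and ALDH5), so that field was not used for grouping, and the level of Aldh2 was examined in each library. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

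The submitters' processing notes name FastQC, STAR 2.4.1d and DESeq2, with GRCm38 as the genome build; the counter, the annotation and the filter on rows are not given in the sources used here. The authors deposited 14145 genes with 1 value per library. The deposited values carry decimals and sum to 265721.2 to 320806.6 per library, and they were treated as the authors' FPKM (read or fragment counts scaled to gene length and library depth). Before the data were examined the design assumed read counts; because the values are FPKM, limma on log2 values replaced the planned count test, and the alternative count tools and scalings named beforehand were not run, the reads recovered from the FPKM being used with limma-voom alone. The authors also deposited a log2 fold change, a p-value, an adjusted p-value and an up or down mark for each gene. Their log2 fold change is infinite for 15 genes, and their adjusted p-values correspond to 24602 genes tested, more than the table lists. No column of values was left without a sample (0 columns).

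Depth was recovered from the FPKM. Multiplied by the exon-union length of the gene in GENCODE M21, which uses GRCm38 and holds 14134 of the genes, the values of a library fall on whole multiples of 1 step. Among genes with 1 to 200 reads, 95.0% to 95.5% lay within 0.05 read of a whole number, against 8.9% to 10.0% with a wrong step. The steps give depths of 17050000 to 18760000 reads or fragments per library; whether reads or read pairs were counted is not given in the sources used here. Floors for genes listed at 0 are 3 reads and cover counting error only.

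Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a variance trend on mean level, on all 14145 genes and all 8 libraries, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. A log2 fold change on this scale understates the change of genes with low FPKM. On simulated data with the spread of each group's own libraries, 14134 genes and 200 changed genes, the test recovered 26.9% of genes changed 2-fold, 80.6% of those changed 4-fold and 89.4% of those changed 8-fold, with 23 false calls. With the spread of the control libraries in both groups the shares were 65.7%, 94.0% and 97.0%, with 12 false calls. In the first of these simulations 18, 54 and 59 genes were recovered, so 23 false calls are a larger share than the threshold of 0.05 should allow. Simulated genes varied independently, without the trend on gene length of the real libraries. The shares therefore do not give the power of the real test.

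Before the data were examined, 44 gene lists were fixed, covering aldehyde and energy metabolism, stress responses, injury and inflammation, and markers of nephron segments and other cell types. The 38 lists with at least 5 measured members, sex-linked transcripts aside, were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. Members were also adjusted over the list alone. Named genes were Aldh2, the 10 higher and 10 lower genes of largest change among those past the threshold with a mean of at least 1 on the log2 scale and no overlap of groups (unnamed gene models left out), and up to 4 members of each list by lowest p. Sex-linked transcripts could be named as checks, and Aldoa is named for its duplicate identifiers. Other genes outside that rule are marked in the text as chosen after their values were seen.

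Sex of each library was read from Xist and Y-linked transcripts. Alternatives fixed beforehand were median-ratio scaling, a replicate block, a sex covariate, limma-voom with sample quality weights on the recovered reads, and leaving out each library. Alternatives added after seeing the data were pseudocounts of 0.1 and 0.5, no variance trend, limma-voom without sample weights, removal of the trend on gene length and GC content per library (lowess, span 0.3) with and without the sex covariate, the male libraries alone, the libraries without knockout 3 and 4, and a filter of FPKM of at least 1 in at least 4 libraries. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.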

Results

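Transcript levels were compared between primary tubular epithelial cells of control mice and of mice lacking Aldh2, the mitochondrial enzyme that oxidises acetaldehyde and lipid-derived aldehydes, in tubular epithelium. The title of the series places the comparison in the setting of tubular cell metabolism and susceptibility to renal injury. Cells were isolated from kidney, grown in culture and left untreated. There were 4 control and 4 knockout libraries, with depths of 17050000 to 17760000 reads or fragments per control library and 17890000 to 18760000 per knockout library, and the values are FPKM for 14145 genes. Every pair of libraries within a group differed by more than sampling noise (chi-square per gene 12 to 337.6), as repeat sequencing of 1 library would not. This does not show that they came from separate animals, which the labels leave unsaid.

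Aldh2 transcript was low in every library labelled knockout. Aldh2 (ENSMUSG00000029455, GRCm38 chromosome 5, 121566027 to 121593824, protein coding) read 31.08, 23.69, 25.45 and 25.19 FPKM in control 1 to 4 and 0.88, 1.64, 1.20 and 1.26 FPKM in knockout 1 to 4. The means were 26.4 ± 3.24 and 1.24 ± 0.31 FPKM (SD, n = 4 each), so the knockouts held 4.71% of the control level, and the log2 fold change of Aldh2 was -3.61 (SE 0.17, limma, adjusted p = 3.43e-05). The FPKM are summed over the whole gene and do not show which exons the remaining Aldh2 reads come from.

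Besides Aldh2, 10 genes passed the threshold, 7 lower and 3 higher in the knockouts. Ehf, an epithelial ETS-family transcription factor, fell from 8.57 ± 1.90 to 1.52 ± 0.26 FPKM (SD, n = 4; log2 fold change -1.91, limma adjusted p = 0.0152). Il1rl1, the receptor of interleukin-33, fell from 19.6 ± 4.78 to 3.48 ± 1.41 FPKM (log2 fold change -2.22, limma adjusted p = 0.0397). Atp8b1, a phospholipid flippase, fell from 3.76 to 0.625 FPKM, Tox3, a high-mobility-group box protein, from 2.51 to 0.429 FPKM, and Tnfsf15, a cytokine of the tumour necrosis factor family, from 2.53 to 0.234 FPKM, at log2 fold changes of -1.55, -1.30 and -1.51. Pepd, the peptidase that splits dipeptides ending in proline, rose from 21.4 ± 5.48 to 61.0 ± 9.15 FPKM (log2 fold change 1.48, limma adjusted p = 0.0416), and Parvb, a focal adhesion protein that binds actin, rose from 2.69 ± 1.01 to 12.2 ± 2.26 FPKM (log2 fold change 1.87, limma adjusted p = 0.0411).

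The remaining 3 genes lie outside the rule for named genes and were chosen after their values were seen. Thbs2, a matricellular glycoprotein, fell from 1.82 to 0.149 FPKM (log2 fold change -1.30), and Gm38357, an unclassified transcript, fell from 2.93 to 0.346 FPKM (log2 fold change -1.54). Hist1h2bj, a histone H2B gene of a family of near-identical copies whose reads can be shared, rose from 0.0921 to 2.79 FPKM (log2 fold change 1.74). The gene is 463 bp long, so its control mean stands for fewer than the 3 reads used here as a floor.

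**Figure D1:**
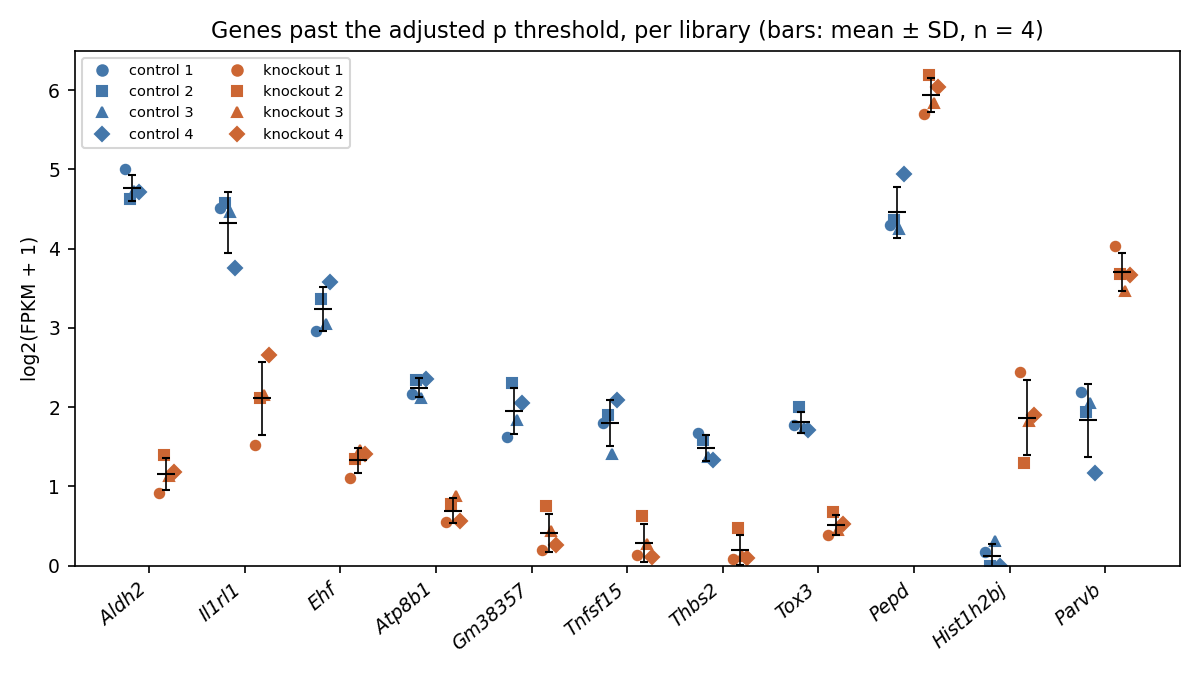
Levels of the 11 genes past the threshold as log2(FPKM + 1), 1 point per library, with the mean and SD of each group (n = 4). For Aldh2 the control points sit at 23.69 to 31.08 FPKM and the knockout points at 0.88 to 1.64 FPKM, and none of the 11 genes has overlapping groups.

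In all, 11 of 14145 genes passed at an adjusted p below 0.05 (8 lower, 3 higher), each changed at least 2-fold, and 2714 genes (19.2%) had an unadjusted p below 0.05. The groups did not overlap for 1644 genes (11.6%), 673 higher and 971 lower in the knockouts. The average share over all splits of the libraries 4 against 4 would be 2.86%. Genes vary together, so single splits can lie far from it, and the share in the other splits was not counted. In the authors' deposited table an adjusted p below 0.05 is given for 53 genes (10 higher and 43 lower), among them the 11, and 808 carry an up or down mark (331 up, 477 down). The count rested on single libraries: without control 1, control 2, control 3, knockout 1 or knockout 4 only Aldh2 passed (1 gene), without knockout 3 there were 3 genes, without knockout 2 there were 1139, and without control 4 there were 8. The 4 controls and knockout 3 and 4 were male and knockout 1 and 2 female by their sex-linked transcripts, and the comparison of male libraries alone, added after seeing the data, called 6275 genes (2496 higher, 3779 lower), the 11 included.

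Other aldehyde and alcohol dehydrogenases were mostly higher in the knockouts. Of 22 measured members besides Aldh2, 15 were higher and 7 lower, with a median log2 difference of 0.26 (camera adjusted p = 0.00719, and adjusted p = 0.462 with an estimated correlation). None passed over all genes, and 7 passed adjusted over the list alone. Aldh1a1, a cytosolic retinaldehyde and aldehyde dehydrogenase, was at 0.84, 1.18, 1.46 and 0.08 FPKM in the controls and at 54.42, 6.11, 7.80 and 3.81 FPKM in knockout 1 to 4 (log2 fold change 2.65, SE 0.67, adjusted p over all genes = 0.138 by limma). Aldh3b1 was at 7.09 ± 0.768 against 14.9 ± 4.53 FPKM, and Adh5, the formaldehyde-clearing alcohol dehydrogenase, at 19.16 to 20.72 against 25.79 to 30.07 FPKM (n = 4 each; SD for Aldh3b1). Aldh1a3 went the other way, at 2.06 ± 1.92 against 0.204 ± 0.0728 FPKM. Without knockout 3 and 4 the list had a median of 0.17 and did not pass camera (adjusted p = 0.102).

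Nuclear and mitochondrial genes of the respiratory chain went in opposite directions. Of 59 nuclear-encoded oxidative phosphorylation genes 55 were higher in the knockouts, with a median log2 difference of 0.47 (camera adjusted p = 3.44e-12, and adjusted p = 0.462 with an estimated correlation), and none passed singly. Ndufs8, a complex I subunit, was at 42.6 ± 1.94 against 73.8 ± 15.5 FPKM, and Ndufb9 at 21.7 ± 2.08 against 42.5 ± 12.4 FPKM (SD, n = 4). All 12 measured mitochondrially encoded transcripts were lower, with a median log2 difference of -0.65 (camera adjusted p = 0.0401, and adjusted p = 0.635 with an estimated correlation), none past the threshold singly. The lowest levels lay in knockout 3 and 4: mt-Co1 was at 4597.19 to 9865.12 FPKM in the controls, at 6328.43 and 6215.38 FPKM in knockout 1 and 2, and at 1708.63 and 1980.31 FPKM in knockout 3 and 4. Without knockout 3 and 4 the nuclear list kept its direction (median 0.25, camera adjusted p = 0.000551) and the mitochondrial list turned to a median of 0.20 (camera adjusted p = 0.210). The nuclear list also consists of short genes, with a median exon-union length of 1718 bp against 3953.5 bp for all genes, and with the trend on length and GC content removed its median was 0.27 (camera adjusted p = 5.47e-06). Its median was -0.02 in knockout 2, within the control libraries.

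A further 5 lists of central metabolism passed camera with higher medians in the knockouts, none with an estimated correlation (adjusted p of 0.462 or 0.619). The 20 glycolysis genes measured stand on 21 rows. Aldoa has 2 gene identifiers, the abundant one higher and the other, at no more than 1.01 FPKM, lower. Of these rows 13 were higher (median 0.37, camera adjusted p = 0.0193), and Pfkm, the muscle-type phosphofructokinase, passed adjusted over the list alone at 9.40 ± 0.863 against 15.9 ± 1.60 FPKM (SD, n = 4). In the pentose phosphate pathway 5 of 7 genes were higher (median 0.60, camera adjusted p = 0.0193), and 3 passed adjusted over the list alone, among them Pgd at 34.5 ± 1.43 against 56.4 ± 12.2 FPKM and Taldo1 at 121.0 ± 16.2 against 223.0 ± 57.4 FPKM. For fatty acid oxidation 21 of 32 genes were higher (median 0.22, camera adjusted p = 0.0077). Slc25a20, the carnitine carrier, was at 7.36 against 12.2 FPKM, while Pdk4, a kinase that restrains glucose oxidation, was at 6.21 against 2.92 FPKM, neither past the threshold. The tricarboxylic acid cycle (15 of 20 higher, median 0.17) and amino acid catabolism (14 of 21 higher, median 0.21) both gave a camera adjusted p of 0.0193, with Sdhb at 33.2 against 57.6 FPKM and Aldh4a1 at 5.19 against 8.44 FPKM. Without knockout 3 and 4 none of the 5 passed (camera adjusted p of 0.541, 0.210, 0.0863, 0.263 and 0.0640 in the order given). Their medians were then 0.08, 0.25, 0.18, 0.16 and 0.18, so those of glycolysis and the pentose phosphate pathway shrank and the other medians changed little.

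Lists of lipid synthesis and related pathways did not pass camera. Gluconeogenesis had a median of 0.19 (adjusted p = 0.163) with Pcx, pyruvate carboxylase, past its list alone at 1.58 against 3.27 FPKM. Fatty acid and triglyceride synthesis had a median of 0.07 (adjusted p = 0.722) with Elovl6, a fatty acid elongase, lower at 3.34 against 1.29 FPKM and past its list alone. Serine and one-carbon metabolism had a median of 0.09 (adjusted p = 0.0757; 0.0288 with the length and GC trend removed) with Psph, which makes serine from phosphoserine, past its list alone at 8.03 against 15.2 FPKM. Cholesterol biosynthesis (median 0.05, adjusted p = 0.532) and peroxisome biogenesis (median 0.06, adjusted p = 0.419) had no member past either threshold.

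Antioxidant and lysosomal genes were higher as groups. Of 22 Nrf2 targets 19 were higher (median 0.52, camera adjusted p = 2.05e-04, and adjusted p = 0.462 with an estimated correlation), and 4 passed adjusted over the list alone. Hmox1, which degrades haem, was at 60.0 ± 3.47 against 97.1 ± 19.6 FPKM, Cbr3, a carbonyl reductase, at 3.66 to 6.95 against 10.13 to 19.22 FPKM, and Ftl1, the ferritin light chain, at 501.0 ± 71.3 against 888.0 ± 143.0 FPKM (SD, n = 4). Of 22 autophagy and lysosome genes 18 were higher (median 0.34, camera adjusted p = 3.13e-04, and adjusted p = 0.462 with an estimated correlation), and 3 passed adjusted over the list alone: Atp6v0d1, a proton pump subunit, at 60.99 to 70.05 against 97.57 to 137.31 FPKM, Map1lc3b at 25.6 ± 2.88 against 45.2 ± 10.9 FPKM, and Hexa, a lysosomal hexosaminidase, at 47.9 ± 14.2 against 87.4 ± 16.7 FPKM. Without knockout 3 and 4 both lists kept a camera adjusted p below the threshold, at 0.00367 and 0.0187. Markers of macrophages, cells that express ferritin and lysosomal genes, were also higher in the knockouts, as given with the cell type lists. Macrophage medians were 2.09 in control 1 and 0.79, 3.00, 0.20 and 2.21 in knockout 1 to 4. Nrf2 medians were -0.14 in control 1 and 0.71, 0.30, 0.47 and 0.55 in knockout 1 to 4. Lysosomal medians were 0.04 and 0.33, 0.25, 0.29 and 0.61 in the same libraries. Control 1 was thus high for macrophage markers alone. Whether macrophages lie behind the 2 lists was not tested.

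Among tubular injury markers 15 of 25 were higher and 10 lower, and the list did not pass (median 0.14, camera adjusted p = 0.536). Adjusted over the list alone, 3 members passed. Cst3, the secreted protease inhibitor cystatin C, was higher at 129.0 ± 4.08 against 295.0 ± 67.1 FPKM (log2 fold change 1.16, SE 0.21). Sox9, a transcription factor of repairing tubules, was lower at 35.7 ± 2.84 against 18.5 ± 4.54 FPKM (log2 fold change -0.94, SE 0.19), and Prom1 was lower at 49.6 ± 11.5 against 20.5 ± 7.90 FPKM (SD, n = 4). The list of epithelial to mesenchymal transition factors mixes mesenchymal and epithelial genes, so its count and median give no direction of that transition. Of its genes 11 of 17 were lower (median -0.17, camera adjusted p = 0.273). Past their list alone were the epithelial genes Grhl2, at 6.50 ± 1.54 against 2.12 ± 1.08 FPKM, and Ocln, a tight junction protein, at 20.3 ± 5.16 against 8.69 ± 4.25 FPKM. The adjusted p of these 5 genes over all genes lay between 0.0924 and 0.141 by limma.

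Markers of distal nephron segments had lower knockout means, and single libraries overlapped. Measured were 4 of 10 loop of Henle, 4 of 9 distal tubule and 5 of 10 principal cell genes. Umod, Slc12a1, Slc12a3 and Aqp2 were not among the genes analysed here. All 4 measured loop of Henle genes were lower (median -1.24), with library medians of -0.84, -0.31, -0.11 and 1.17 in control 1 to 4 and of -1.45, -1.26, -0.66 and -1.28 in knockout 1 to 4. Of these genes 3 passed adjusted over the list alone, with Cldn19, a claudin of the thick ascending limb, at 4.27 ± 3.33 against 0.961 ± 0.638 FPKM. In the distal convoluted and connecting tubule list 3 of 4 were lower (median -0.29), with the magnesium channel Trpm6 at 7.88 ± 5.80 against 2.23 ± 1.04 FPKM; both lists were too short for camera. All 5 measured principal cell genes of the collecting duct were lower (median -0.67, camera adjusted p = 0.0450, and adjusted p = 0.462 with an estimated correlation), with Scnn1g, a subunit of the epithelial sodium channel, at 3.80 ± 1.91 against 0.934 ± 0.788 FPKM. Without knockout 3 and 4 the median of the principal cell list was -1.40 (camera adjusted p = 0.00328), and with the length and GC trend removed -1.04 (camera adjusted p = 0.00629). Among the male libraries alone it was -0.37 (camera adjusted p = 0.711), and control 1, at -0.69, lay below knockout 3, at 0.02, and knockout 4, at -0.45. Of 37 proximal tubule genes 19 were measured, 10 higher and 9 lower (median 0.09, camera adjusted p = 0.792); Slc4a4, the basolateral bicarbonate cotransporter, passed its list alone at 12.4 ± 4.83 against 3.84 ± 2.42 FPKM. Intercalated cell (2 genes, median 0.09) and urothelial markers (2 genes, median -0.21) were not tested, and podocyte and parietal markers had a median of -0.25 over 7 genes (camera adjusted p = 0.532).

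Markers of cells other than tubular epithelium varied within both groups. All 12 measured macrophage and leukocyte markers had higher knockout means (median 1.66, camera adjusted p = 2.05e-04, and adjusted p = 0.619 with an estimated correlation). Lyz2, lysozyme, was at 674.09, 16.89, 26.10 and 9.38 FPKM in control 1 to 4 and at 397.75, 990.32, 82.57 and 553.64 FPKM in knockout 1 to 4, and C1qb at 77.22, 17.25, 17.55 and 2.28 against 46.52, 164.91, 29.65 and 114.33 FPKM, so control 1 lay among the knockouts. Antigen presentation genes were higher in 14 of 15 cases (median 0.38, camera adjusted p = 0.00229, and adjusted p = 0.619 with an estimated correlation), with Psmb10, an immunoproteasome subunit, at 8.86 against 14.1 FPKM. For this list without knockout 3 and 4 the median was 0.23 (camera adjusted p = 0.242), and with the length and GC trend removed it was 0.21 (camera adjusted p = 0.138). Endothelial markers were lower in 4 of 5 cases (median -0.37, camera adjusted p = 0.0487, and adjusted p = 0.462 with an estimated correlation), Eng at 4.54 ± 0.774 against 1.68 ± 0.713 FPKM and Esam at 0.883 ± 0.201 against 0.192 ± 0.158 FPKM (SD, n = 4), both past their list alone. For endothelium fry gave an adjusted p of 0.0338. Without knockout 3 and 4 the endothelial median was -0.18 (camera adjusted p = 0.0935), and with the length and GC trend removed it was -0.09 (camera adjusted p = 0.141). Fibroblast and pericyte markers had a median of -0.70 over 10 genes (camera adjusted p = 0.280), with Pdgfrb at 17.25, 3.62, 5.41 and 4.38 FPKM in the controls and 0.65, 1.35, 2.62 and 1.75 FPKM in the knockouts. None of 7 erythrocyte markers was among the genes analysed here (0 measured).

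Proliferation and DNA repair genes were lower as groups. Of 40 cell cycle genes 34 were lower (median -0.30, camera adjusted p = 0.0077), and of 20 DNA crosslink repair genes 17 were lower (median -0.29, camera adjusted p = 0.0450), none past the threshold singly. With an estimated correlation the adjusted p of the 2 lists was 0.635 and 0.619. Top2a, a topoisomerase of dividing cells, was at 4.4 to 7.54 FPKM in the controls and at 2.28, 6.96, 0.92 and 1.80 FPKM in knockout 1 to 4. Rev3l, a subunit of a translesion DNA polymerase, was at 5.85 ± 2.08 against 2.47 ± 1.82 FPKM (SD, n = 4). Without knockout 3 and 4 the medians were -0.11 and -0.19 (camera adjusted p of 0.431 and 0.162). The DNA crosslink repair genes are long, with a median exon-union length of 6408.5 bp, and with the trend on length and GC content removed their median was 0.01 (camera adjusted p = 0.980). Knockout 2 had list medians of 0.21 and 0.00, at the level of the control libraries.

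The remaining stress and inflammation lists did not pass camera over all 8 libraries. Endoplasmic reticulum chaperones and unfolded protein response genes had a median of 0.08 (adjusted p = 0.0632), and of 0.33 without knockout 3 and 4 (adjusted p = 0.0171), with Sdf2l1, a chaperone partner, past its list alone at 14.0 ± 2.70 against 27.6 ± 4.12 FPKM. Interferon-stimulated genes had a median of -0.05 (adjusted p = 0.938), with Ifi27 past its list alone at 23.7 ± 4.56 against 41.4 ± 4.18 FPKM. Immediate early genes were lower in 15 of 17 cases (median -0.35, adjusted p = 0.0798). For these genes camera passed with the length and GC trend removed (median -0.52, adjusted p = 0.000153) and without knockout 3 and 4 (median -0.46, adjusted p = 0.000551), while the male libraries alone gave a median of 0.01 (adjusted p = 0.918). The medians were 0.24 for ferroptosis regulators (adjusted p = 0.0819), 0.18 for the integrated stress response (adjusted p = 0.0819), 0.06 for p53 targets (adjusted p = 0.417), 0.17 for senescence-associated secreted factors (adjusted p = 0.573) and -0.07 for NF-kB and chemokine genes (adjusted p = 0.469). They were -0.03 for the heat shock response (adjusted p = 0.439), -0.07 for targets of the hypoxia-inducible factor (adjusted p = 0.853), -0.06 for apoptosis and pyroptosis (adjusted p = 0.891) and -0.14 for extracellular matrix and fibrosis (adjusted p = 0.960). For these last 4 lists and the interferon list camera's direction was up, against the sign of the median. Over the 38 lists tested, 16 passed camera (11 higher, 5 lower), 0 with an estimated correlation (3 at an unadjusted p below 0.05) and 1 by fry.

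**Figure D2:**
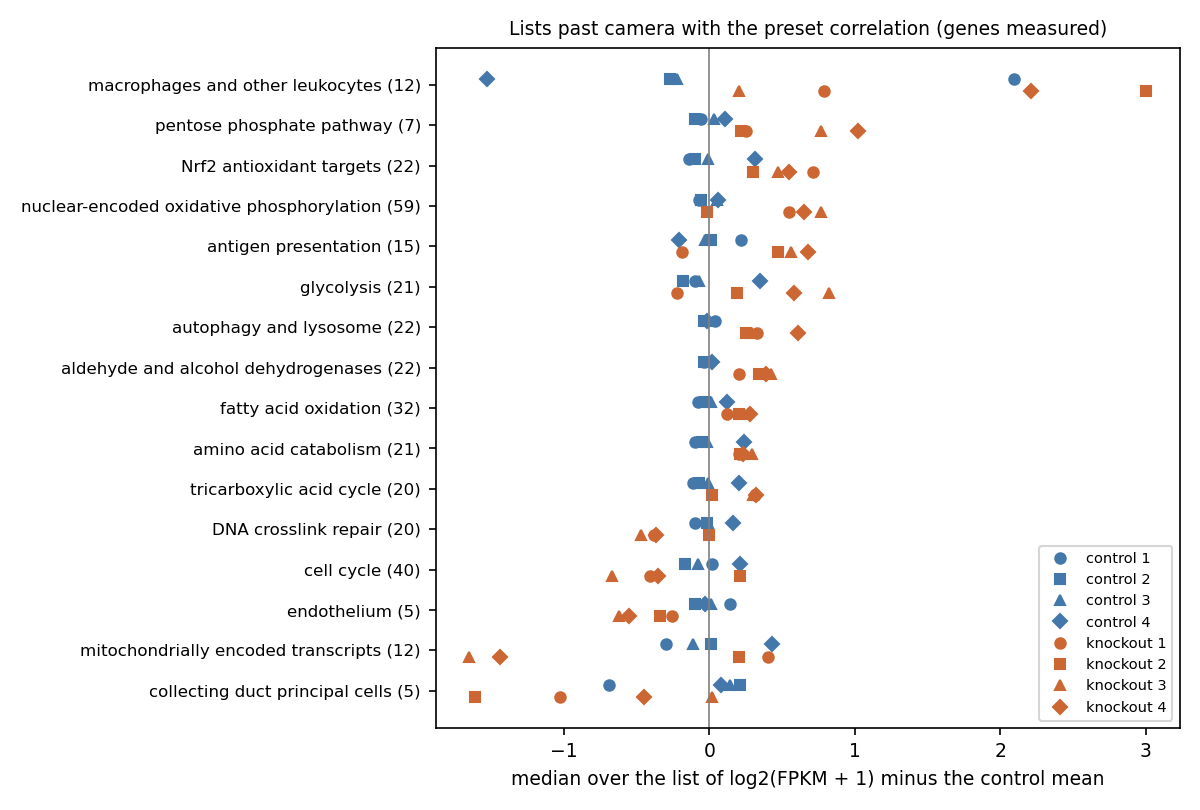
Median over each of the 16 lists past camera of the difference of log2(FPKM + 1) from the control mean, 1 point per library, with the number of genes measured. Knockout 3 and 4 sit at -1.65 and -1.44 for the mitochondrially encoded transcripts, and control 1 at 2.09 for the macrophage markers.

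The knockout libraries differed among themselves in sex, in mitochondrial RNA and in gene length. Xist was at 14.53 and 38.31 FPKM in knockout 1 and 2 and at 0.00 or 0.01 FPKM in the other libraries, where 3 reads would give 0.00891 to 0.0098 FPKM. The Y-linked helicase Ddx3y was listed at 0 in knockout 1 and 2, and was at 6.15 to 15.51 FPKM in the controls and 1.48 and 4.39 FPKM in knockout 3 and 4. Mitochondrially encoded genes made up 4.35% to 7.68% of the FPKM in the controls, 5.25% and 5.57% in knockout 1 and 2, and 1.29% and 1.60% in knockout 3 and 4. Over the 2726 protein-coding genes of shortest exon-union length (243 to 2847 bp), the median difference from the control mean was 0.21, 0.06, 0.39 and 0.41 on the log2 scale in knockout 1 to 4; over the 2722 longest (6851 to 41324 bp) it was -0.31, 0.00, -0.71 and -0.50. Among the male libraries 1063 of the shortest genes were called higher and 241 lower, against 153 higher and 1514 lower among the longest. With the trend on length and GC content removed, 2 genes passed over all 8 libraries, Aldh2 and Tox3. Among the male libraries alone camera no longer passed for macrophage markers (adjusted p = 0.169), principal cells (0.711), endothelium (0.392), DNA crosslink repair (0.224) and amino acid catabolism (0.0934), and it passed for the integrated stress response (0.00299). In the order given, the medians of the lists that lost the call were 1.19, -0.37, -0.59, -0.42 and 0.20 there, against 1.66, -0.67, -0.37, -0.29 and 0.21 over all 8 libraries.

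**Figure D3:**
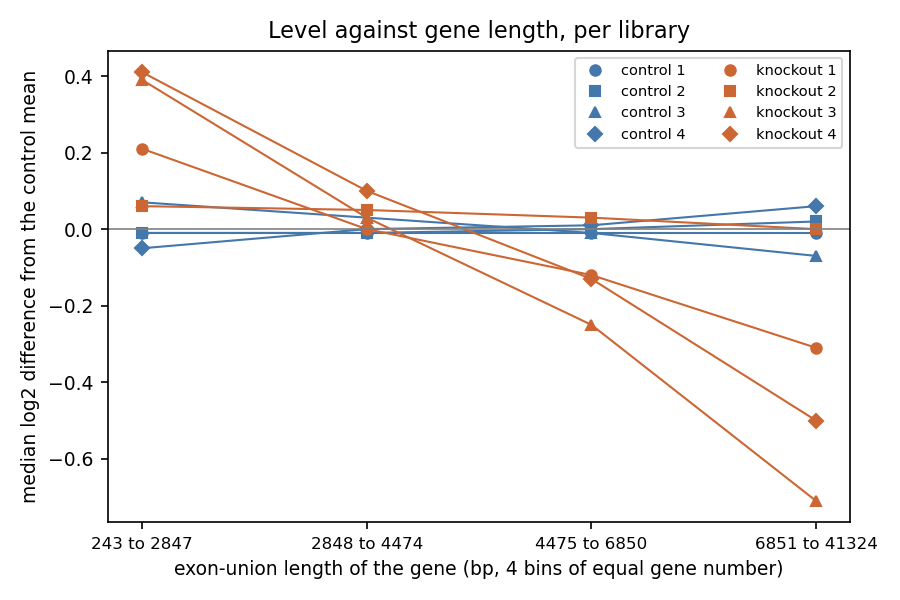
Median difference from the control mean on the log2 scale (y axis) over 4 bins of protein-coding genes by exon-union length in bp (x axis), 1 line per library. Knockout 1, 3 and 4 run from 0.21, 0.39 and 0.41 in the shortest bin to -0.31, -0.71 and -0.50 in the longest, and knockout 2 from 0.06 to 0.00.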

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

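The tests in this part were chosen after the results they bear on were seen. In 196 groups of 4 libraries (the genes named in the text and the list medians), 22 had a library far from the other 3. The cutoff flags about 1 in 20 groups of independent, normally distributed values. Genes were taken as FPKM, not on the log2 scale, and all groups share the same libraries. The 22 are therefore not shown to exceed chance. Control 4 stood apart for Il1rl1 (12.49 FPKM), Pepd (29.6 FPKM), Aldh4a1 (6.77 FPKM), Cldn19 (9.23 FPKM) and Elovl6 (4.66 FPKM), and in the list medians of peroxisome biogenesis (0.09), p53 targets (-0.57), targets of the hypoxia-inducible factor (0.21) and proximal tubule (0.87). Control 1 stood apart for Ndufb9 (18.59 FPKM), Lyz2 (674.09 FPKM), Pdgfrb (17.25 FPKM) and Bgn (70.53 FPKM), and in the list medians of apoptosis and pyroptosis (0.08) and principal cells (-0.69). Knockout 1 stood apart for Aldh1a1 (54.42 FPKM), Aldh3b1 (8.17 FPKM) and Hmox1 (126.33 FPKM). Knockout 2 stood apart for Thbs2 (0.39 FPKM), Esam (0.43 FPKM) and the tricarboxylic acid cycle median (0.02), and knockout 4 for Ifi27 (47.62 FPKM).

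The 11 genes past the threshold, Aldh2, Il1rl1 and Ehf among them, separated the groups more than other splits did. Only the real split of the 8 libraries called as many genes (1 of 35, 11 genes against at most 4). As 1 of 35 is the smallest share the splits can give, and the count was chosen after it was seen, the splits do not exclude chance. Aldh2 was removed by design, which leaves 10 genes against 4. Every called gene in the splits changed at least 2-fold (1 of 35, 11 against 4), so that count adds no further test, and the larger direction gave 8 against 4 (1 of 35). Among the male libraries alone, where sex does not differ, 11 of 11 were called and kept over 0.5 of their log2 fold change. Those libraries were among the ones that chose the 11, and 6275 of 14145 genes were called in them. The count is thus no separate test of sex as the cause. In the male libraries Il1rl1 was at -1.92 (SE 0.27), and Aldh2, named before the data were examined, at -3.61 (limma adjusted p = 0.000607). The length trend was smaller than the changes of the 11 genes. The median log2 fold change ran from 0.25 over the shortest protein-coding genes to -0.37 over the longest. The smallest change of the 11 was -1.30 (Thbs2 and Tox3). With the trend removed 11 of 11 kept over 0.5 of their log2 fold change. A trend of this size could hardly prevent that, so the count is no separate test. Il1rl1 moved from -2.22 (SE 0.28) to -1.81 (SE 0.41) and Atp8b1 from -1.55 (SE 0.16) to -1.23 (SE 0.21). For 9 genes the call ended (limma adjusted p of 0.074 to 0.101) as folds shrank or errors grew. Loss of Aldh2 and any other difference between the 2 groups of mice or cultures remain open, as nothing in the labels separates them.

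For the gene lists chance was not excluded either, since 4 of the 35 splits gave at least the 16 lists of the real one, with 19 as the highest of the others.

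Short genes were higher and long genes lower in knockout 1, 3 and 4. The slope of the difference from the control mean was -0.209, -0.037, -0.389 and -0.316 on the log2 scale per doubling of length in knockout 1 to 4, against -0.073 to 0.054 in the controls. Genotype acting alike in each library would need all 4 slopes below the controls by more than the control range, and 3 were, but a single library does not exclude it. RNA or library quality of single libraries, which may differ within a genotype, goes with the range of 0.352 among the knockout slopes, but no quality measure was used here to decide. Genotype and quality cannot be told apart for this trend.

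Mitochondrially encoded transcripts such as mt-Co1 were low in knockout 3 and 4, as were the nuclear-retained RNAs Malat1 (11.4 and 13.3 FPKM, against 41.7 to 131 FPKM in the other 6 libraries) and Neat1 (1.52 and 1.85 FPKM, against 3.65 to 7.99 FPKM); both were chosen after their values were seen. Male sex by itself is argued against, as the lowest male control lay 1.28 above the higher male knockout on the log2 scale, with a control range of 0.76. An effect of the knockout in males only stays open, as knockout 3 and 4 are the only male knockouts and no control was female. The length trend goes the other way. The mitochondrial transcripts are short (median 870.5 bp), and the shortest protein-coding genes were higher in knockout 3 and 4 (0.39 and 0.41). Length and GC content together as the whole cause are argued against by a gap of 1.09 that stayed once both trends were removed (control range then 0.60). Genotype acting in each knockout library stays open. Knockout 1 and 2 lay within the controls as deposited (9.91 and 9.83 against 9.65 to 10.42). With the length and GC trend removed knockout 1 was at 9.15, below the controls (9.72 to 10.32), so only 1 library, knockout 2, lay at or above the lowest control in both. The 6275 calls among the male libraries did not come with any pair of libraries of 1 sex: the female pair, knockout 1 and 2, gave 14 against the same controls, and the 4 mixed pairs gave 1 each. A shared handling step of knockout 3 and 4 was not tested, as the labels used here give no batch.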

How the results depend on the processing

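The Aldh2 log2 fold change stayed past the threshold under every setting run, at -4.43 to -3.53, and the median-ratio scaling, the pseudocount of 0.5 and the fit with no variance trend gave 11 genes each. The FPKM filter gave 12 (3 higher, 9 lower), the 11 among them. A replicate block left 1 gene (0 higher, 1 lower, 1 at least 2-fold). In their deviations from the group means, same-numbered libraries correlated at 0.04, -0.21, 0.61 and -0.04. Differently numbered ones correlated at -0.65 to 0.40. These values do not settle whether the numbers pair the samples. Sample quality weights with limma-voom gave 7503 genes (3167 higher, 4336 lower, 2728 at least 2-fold). Those weights were 0.64 to 4.96 in the controls and 0.15, 0.24, 0.58 and 3.27 in knockout 1 to 4. Most of the knockout weight in that fit was thus on knockout 4. A sex covariate gave 4838 genes (1780, 3058, 1663), and the male libraries alone 6275 (2496, 3779, 1712). Both sex settings estimate the difference from the controls and knockout 3 and 4, since no control was female. Limma-voom without weights gave 7 genes (0 higher, 7 lower, 7 at least 2-fold), the pseudocount of 0.1 gave 3 (0, 3, 3), removal of the length and GC trend 2 (0, 2, 2), and that removal with the sex covariate 2090 (1101, 989, 478). Leaving out each library gave 1 to 1139 genes changed, 0 to 392 higher, 1 to 747 lower and 1 to 473 at least 2-fold, the highest without knockout 2, and an Aldh2 log2 fold change of -3.69 to -3.53. Lists past camera numbered 12 to 18 on leaving out a library (8 of the 16 kept their call whichever was left out, and glycolysis, the tricarboxylic acid cycle, amino acid catabolism, mitochondrially encoded transcripts, cell cycle, DNA crosslink repair, principal cells and endothelium lost it at least once), 7 without knockout 3 and 4, 0 with an estimated correlation and 1 by fry. Mitochondrially encoded transcripts reversed to 0.20 without knockout 3 and 4, and DNA crosslink repair to 0.10 with the length and GC trend removed and the sex covariate. Except where stated, the cause was not tested. Other count tools, count scalings and a filter on counts, named beforehand, were not run: the table holds no counts, and the reads inferred from the FPKM were used with limma-voom alone. At 17050000 to 18760000 reads or fragments per library, Xist could be seen down to 0.0098 FPKM in any library.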

Other observations

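Of the tests in this part only that of the neighbours of Aldh2 was written before its result was seen.

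Some list genes not set out with the comparisons differed widely between libraries. Cdkn2a, the cell cycle inhibitor locus that accumulates in cultured and senescent cells, was at 70.50, 40.09, 49.25 and 12.40 FPKM in control 1 to 4 and at 140.22, 69.49, 164.08 and 162.58 FPKM in knockout 1 to 4 (log2 fold change 1.77, SE 0.49, adjusted p = 0.154 by limma). Acta2, smooth muscle actin, was at 440.0 ± 262.0 against 1040.0 ± 523.0 FPKM (SD, n = 4), while Bgn, a matrix proteoglycan, was at 70.53, 18.77, 21.79 and 14.37 FPKM in control 1 to 4 and at 4.96, 6.21, 9.85 and 7.27 FPKM in knockout 1 to 4, neither past the threshold. Cdh1, the epithelial cadherin, was at 125.43, 208.42, 209.78 and 107.82 FPKM in control 1 to 4 and at 41.31, 30.10, 155.82 and 87.81 FPKM in knockout 1 to 4.

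A smaller share of distal segment cells in the knockout cultures may lie behind the lower levels of Cldn19, Trpm6 and Scnn1g. Of the 13 measured markers of the loop of Henle, distal tubule and principal cell lists, 12 were lower (mean -0.78, SD 0.50). Umod, Slc12a1, Slc12a3 and Aqp2, also on these lists, were not measured, so the remaining markers may not follow the share of such cells. These lists were joined because they had been seen to be lower, and the intercalated cell list (1 gene higher, 1 lower) was left out, so the count is a description. The medians were -0.63, 0.11, -0.02 and 0.54 in control 1 to 4 and -1.13, -1.02, -0.36 and -0.63 in knockout 1 to 4, so control 1 lay among the knockouts and the question stays open. A change in these genes within the same cells was not tested.

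Variants linked to the targeted allele could change genes near Aldh2. Within 5 Mb of Aldh2 on chromosome 5, 26 of 113 genes (23%) had an unadjusted p below 0.05, against 2687 of 14031 other genes (19.2%; 1-sided Fisher's exact test across genes, which are not independent, p = 0.178), and 0 of the 113 passed the adjusted threshold by limma. The share near Aldh2 was higher, by no more than chance allows at this window, so linked variants stay open.

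Y-linked transcripts Ddx3y, Uty, Kdm5d and Eif2s3y are among the 53 genes with an adjusted p below 0.05 in the authors' deposited table (4 genes). Knockout 1 and 2 were female while all controls were male, but sex is not the whole of it: the 4 genes were also called lower among the male libraries alone (median log2 difference of the sex-linked list -1.12). That fit called 3779 of 14145 genes lower, 1514 of them among the 2722 longest protein-coding genes. Lower calls were thus not limited to Y-linked genes. The median exon-union length of the sex-linked list, 9791 bp, includes Xist and does not give that of the 4 Y-linked genes. Whether gene length accounts for their fall was not tested. The FPKM of the 4 Y-linked genes summed to 5.79 and 12.16 in knockout 3 and 4, against 19.96 to 34.1 in the controls.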
